A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

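Total RNA was extracted with hot acid phenol from yeast cultures grown in rich medium (YPD) at 30 C to an optical density (OD600) of 0.7, per the labels' protocols. For each sample 1 ug of total RNA was converted to biotin-labelled cRNA with an in vitro transcription kit and hybridised to 1 Affymetrix Yeast Genome array, per the labels' protocols. The array is a 1-colour oligonucleotide array in which several short probes form a probe set for each transcript.

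The deposited values are intensity values per probe set and array on a linear scale, made with RMA per the submitters' processing notes. RMA is a method that corrects the background, makes the intensity distributions of the arrays alike by quantile normalization and summarises the probes of a probe set. Its software version, the probe sets it was run over and the step that returned the values to the linear scale are not given in the sources used here. The linear scale was read from the values themselves, which ran from 15.2 to 35540, and log2 was taken before every test. The design had been written for values already on the log2 scale, and the test was kept otherwise as planned. The median intensity per array was 625 and 713 in wt, 630 and 644 in dot1, 628 and 623 in swi4, and 632 and 639 in ard1 (replicates 1 and 2). The median of wt replicate 2 stands apart from the other 7, although RMA makes the probe intensities of arrays alike, and this bears on every change against wt. Signal over background cannot be read from these values, because RMA had removed the background before deposit. The 8 arrays were all used, and their number limits the precision.

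The table held 5814 probe sets. Of these, 5498 had 1 gene symbol in the platform's annotation, 98 were control or reporter probe sets, 218 had no gene name in the tables used here, and 0 had several symbols. Symbols were brought up to date through a gene table of the R64 assembly, which changed 12 of them, and all 5449 genes tested were found in that table. For the 47 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays was used. There were 117 genes represented by a probe set that the array's design marks as shared between transcripts, and their values are uncertain because they may hold signal of a near-identical copy. Control, reporter and unnamed probe sets were left out of the fits over genes and were examined separately. The labels give replicate numbers 1 and 2 in each group, and no array was left out.

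Differences between groups were estimated with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) in 1 fit over the 8 arrays with 4 group means. This left 4 residual degrees of freedom, and the empirical Bayes prior added 2.73. Calls were two-sided with a Benjamini-Hochberg adjusted p under 0.05 over the 5449 genes, within each comparison. Unless a different source is named, an adjusted p in the text comes from limma and an error is the standard error (SE) of the limma estimate on the log2 scale, with n = 2 arrays per group. The words rose and fell are used of genes that passed this threshold. Comparisons were each mutant against wt and each pair of mutants. The smallest two-sided exact permutation p with 2 arrays per group is 0.333, so no single gene could reach the threshold by permutation.

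Fixed gene lists were tested as sets with camera (preset inter-gene correlation 0.01) and, as alternatives, with camera using an estimated correlation and with fry, each adjusted over the 99 tests of 33 lists in 3 mutants. Lists needed at least 3 measured members. They covered the silent mating cassettes, a-specific, alpha-specific and haploid-specific genes, pheromone response, sporulation and meiosis, silencing factors, histone methylation and H2B ubiquitination. They also covered N-terminal acetyltransferases, the COS family, seripauperin and TIR/DAN genes, flocculins, SBF targets, MBF targets, SBF and MBF subunits, histone genes and the CLB2 cluster. The others were the Msn2 and Msn4 stress response, heat shock chaperones, cytosolic ribosomal proteins, ribosome biogenesis, amino acid biosynthesis, methionine and sulfur metabolism, the phosphate and iron regulons, hexose transporters, glycolysis, gluconeogenesis and the glyoxylate cycle, the respiratory chain, the proteasome, auxotrophic markers and cell wall integrity. The mating-type locus genes and the helicases of the Y' telomere elements were listed too. Of these, 0 of 2 and 0 of 8 were among the genes tested, so they are not analysed here. Of the 33 lists tested, 1 counts in these adjustments and is not used here otherwise.

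Subtelomeric genes were planned as those within 20 kb of a chromosome end. Because the build behind the array's annotation could not be matched to the gene table, no coordinates were used, and the planned fallback was taken: the genes with the 8 highest systematic numbers on each of the 32 chromosome arms. Their calls were compared with those of all other genes by two-sided Fisher's exact tests, adjusted over the 6 comparisons separately for rises and for falls, and their median change was set against 10000 random gene sets matched on the wt level.

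The mapping of samples, the tests, the lists, the named genes and the alternatives were fixed before the data were examined. The named genes were the 3 deleted genes and the 2 genes flanking each, the mating cassettes, and per mutant the 10 largest rises and 10 largest falls among called genes whose 2 mutant arrays both lay beyond both wt arrays. Added were up to 10 called subtelomeric genes per mutant by size of change, and up to 4 members per list and mutant with the smallest adjusted p. The alternatives were the replicate number as a block, a fit of only the 2 groups compared, median centring, quantile normalization over the genes, and leaving out the dimmest 25% of genes. Further alternatives were eBayes with trend and robust options, the mean of a gene's probe sets, a 2-fold threshold, an adjusted p under 0.01, other widths of the subtelomere (4 or 16 genes per arm), repeated families left out, and each array left out in turn.

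The fit was tested on simulated data with 100 genes changed by 1 log2 unit and 100 by 2 log2 units among the 5449 genes, for each mutant. Of the genes changed by 1 unit, 96% were recovered in dot1, 96% in swi4 and 91% in ard1. Of those changed by 2 units, 100%, 100% and 99% were recovered. The false calls were 7 of 203 in dot1, 13 of 209 in swi4 and 9 of 199 in ard1. The simulated arrays had independent noise, the same spread in all groups and no array-wide shift. These rates therefore do not show how the fit behaves with the unequal spread and the higher median of wt replicate 2 in the real data. Nor do they cover deviations shared by same-numbered arrays. The 3 mutant comparisons share the same wt arrays. The correlation of their changes was therefore set against 100 simulations of unchanged groups that share simulated wt arrays.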

Results

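Transcript levels were measured in 4 groups of budding yeast (Saccharomyces cerevisiae) cultures, a wild type (wt) and strains deleted for DOT1, SWI4 or ARD1. Each group had 2 arrays that the labels call biological replicates. Dot1 is the methyltransferase that acts on a lysine in the core of histone H3. Swi4 is the DNA-binding subunit of SBF, a transcription factor of the start of the cell cycle, and Ard1 is the catalytic subunit of NatA, the main N-terminal protein acetyltransferase. The title of the series sets these strains in the question of how Dot1 and its histone mark bear on silencing, both in natural heterochromatin near chromosome ends and at HML and HMR, the silent copies of mating-type genes. The 2 wt arrays differed more than the replicates of swi4 and ard1. The SD of the difference between replicates over genes was 0.32 on the log2 scale in wt, 0.30 in dot1, 0.14 in swi4 and 0.17 in ard1. In wt, replicate 2 lay above replicate 1 by a median of 0.14, by 0.18 in the dimmest 25% of genes and 0.12 in the others. The median change of all genes against wt was −0.07 in dot1, −0.10 in swi4 and −0.07 in ard1, and 0.01, 0.00 and 0.01 after median centring, a shift of just over 0.1 in swi4. Changes are given without that centring, and splits of direction are given both ways where they differ.

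Each deleted gene was low in its own mutant. DOT1 was 9.95-fold lower in dot1 than in wt (log2 change −3.31 ± 0.15, adjusted p = 0.00106), at log2 intensities of 4.49 and 4.29 against 7.49 and 7.92. The dot1 arrays lay near the lowest gene mean of 4.02, so this fold is a lower bound. ARD1 was 37.5-fold lower in ard1 (−5.23 ± 0.18, adjusted p = 1.29e-04), at 5.57 and 5.22 against 10.41 and 10.83. SWI4 fell in swi4 (−0.91 ± 0.14, adjusted p = 0.0130), at 4.21 and 4.22 against 5.14 and 5.11 in wt. It was dim in both groups and near that floor in swi4, so the size of its fall is a lower bound. Without swi4 replicate 1 or replicate 2 the fall of SWI4 was −0.90 and −0.91 and its adjusted p was above the threshold, at 0.118 and 0.0967. Of the genes that flank the deletions, LRS4 and APT2 beside DOT1, KAP123 and LSM4 beside SWI4, and VPS29 and SPO13 beside ARD1, only KAP123, a nuclear import receptor gene, was called in the mutant of its own neighbour. It fell by 0.36 ± 0.08 in swi4, where APT2 also fell, by 0.50 ± 0.10. In dot1, KAP123 and APT2 changed by −0.40 ± 0.08 and −0.39 ± 0.10 without passing the threshold (limma, adjusted p = 0.0565 and 0.0862).

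**Figure D1:**
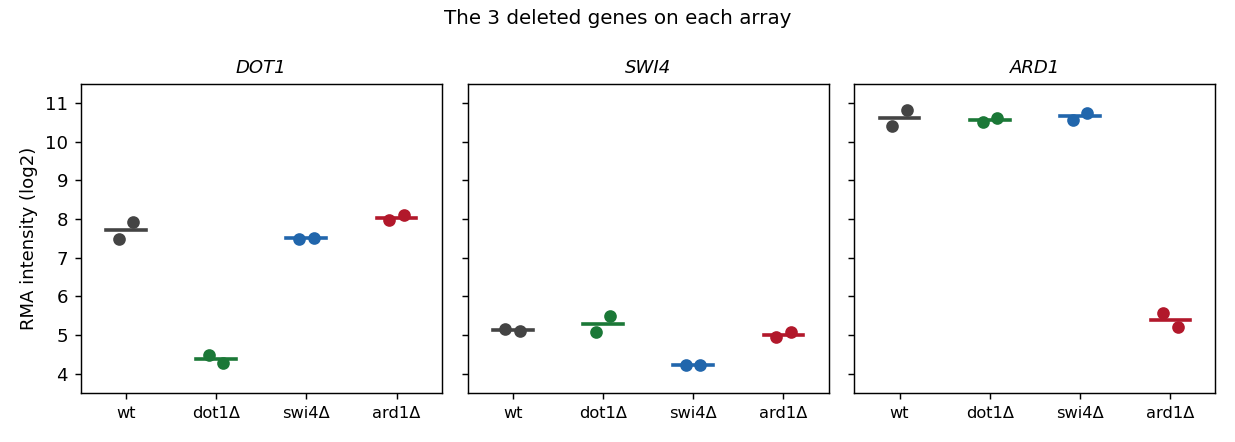
RMA intensity (log2) of DOT1, SWI4 and ARD1 on each of the 8 arrays, by strain; points are arrays and bars are group means of 2 arrays. DOT1 and ARD1 fell to 4.29 and 5.22 at the lowest in their own mutants, and SWI4 lay at 4.21 and 4.22 in swi4 against 5.14 and 5.11 in wt.

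None of the 3 measured genes of the silent mating cassettes rose in any mutant. HMRA1, which encodes the a1 repressor at HMR, changed by 0.02 in dot1, 0.04 in swi4 and 0.00 in ard1 (SE 0.08), at a mean level of 4.11 below which only 6 genes lay. HMLALPHA1, the activator of alpha-specific genes, gave −0.09, −0.25 and −0.34 (SE 0.12), and HMRA2 gave 0.04, −0.35 and −0.55 (SE 0.12). The last was a called fall (adjusted p = 0.0248) that was lost when leaving out any 1 of wt replicate 1, wt replicate 2, ard1 replicate 1 or ard1 replicate 2. The probe sets of HMLALPHA1 and HMRA2 are shared with near-identical copies, so their values are uncertain. The genes of the active mating-type locus were not measured separately (0 of 2). Signal of an active copy could mask a rise from a silent one, so these 2 genes cannot show whether silencing was kept. Of the 3 measured cassette genes, 0, 0 and 1 were called in dot1, swi4 and ard1 (0, 0 and 2 adjusted over the list alone, and 0, 1 and 2 at an unadjusted p under 0.05 in limma), all of them downward. Among 7 a-specific genes, which mark a-type cells, limma called 0 in each mutant (0 adjusted over the list alone; 0, 2 and 2 at an unadjusted p under 0.05), with medians of 0.00, 0.14 and −0.19. The camera test did not pass in any mutant for either list (for ard1, adjusted p = 0.31 and 0.459). Without wt replicate 2, 1 a-specific gene was called lower in ard1, and without wt replicate 1 the a-specific list passed camera in swi4 (adjusted p = 0.0350).

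In dot1 the largest rise was that of HSP26, a small heat shock chaperone gene, at 9.60-fold (3.26 ± 0.20, adjusted p = 0.00208). The oligopeptide transporter gene OPT2 rose 5.62-fold (2.49 ± 0.18), SSA4, a stress-induced Hsp70, 4.26-fold (2.09 ± 0.15) and HIS4, a histidine synthesis gene, 2.35-fold (1.23 ± 0.10). Besides DOT1, the falls included YMR230W-A (3.48-fold lower, −1.80 ± 0.10), YDR042C (−1.75 ± 0.22), ZPS1 (−1.23 ± 0.15), the alcohol acetyltransferase gene ATF2 (−1.22 ± 0.15) and the RNA helicase gene DBP2 (−1.14 ± 0.15). In all, 61 genes rose and 73 fell of 5449, and 14 and 14 did so by at least 2-fold.

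Of 21 heat shock chaperone genes 5 rose in dot1 (8 adjusted over the list alone): HSP26, SSA4, the mitochondrial disaggregase gene HSP78 (0.92 ± 0.13), and the Hsp90 cofactor genes CPR6 (0.56 ± 0.08) and AHA1 (0.55 ± 0.09). The list passed camera (adjusted p = 1.92e-09; adjusted p = 0.481 with an estimated correlation). Of 22 Msn2 and Msn4 stress genes 2 rose in dot1, HSP26 and SSA4, which the chaperone list also holds, and 15 rose adjusted over the list alone. For these stress genes camera gave adjusted p = 5.71e-11, and adjusted p = 0.5 with an estimated correlation. In the methionine and sulfur list 3 of 21 genes rose, MET14 (0.98 ± 0.10), MET1 (0.84 ± 0.11) and MET5 (0.70), which act in sulfate assimilation, with 13 up and 1 down adjusted over the list alone. For this sulfur list camera gave adjusted p = 3.87e-09, and adjusted p = 0.481 with an estimated correlation. Of 34 amino acid biosynthesis genes 4 rose in dot1 (5 adjusted over the list alone), HIS4, ARG1 (0.88 ± 0.14), ARG4 (0.81) and HIS5 (0.53). For the amino acid list camera gave adjusted p = 4.00e-06, and adjusted p = 0.481 with an estimated correlation. All 33 respiratory chain genes had positive changes in dot1 (median 0.46), and 4 rose (27 adjusted over the list alone), among them QCR6 (0.84 ± 0.15) and QCR2 (0.63 ± 0.08) of the cytochrome bc1 complex. For the respiratory chain list camera gave adjusted p = 1.35e-20, and adjusted p = 0.481 with an estimated correlation. All 50 ribosome biogenesis genes had negative changes (median −0.73), of which 1 was called, NSR1 (−0.67 ± 0.11), a nucleolar protein gene, and 27 were called adjusted over the list alone. For ribosome biogenesis camera gave adjusted p = 4.19e-11, and adjusted p = 0.766 with an estimated correlation.

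These dot1 counts depended on single arrays and on the other groups in the fit. With only dot1 and wt fitted, limma called 0 genes, DOT1 included (618 genes at an unadjusted p under 0.05). Of 134 genes called, 11 were called without wt replicate 2, 12 without dot1 replicate 1, 4 without dot1 replicate 2 and 807 without wt replicate 1. Median centring gave 119 up and 114 down and quantile normalization 113 up and 102 down. Of the 44 calls of named genes in dot1, 3 were made whichever of the 4 arrays compared was left out: HSP26, OPT2 and YMR230W-A. Without wt replicate 1, 28 ribosome biogenesis genes, 12 respiratory chain genes, 10 stress genes and 10 sulfur genes were called. Without wt replicate 2 there were 0, 0, 2 and 1. Without dot1 replicate 1 there were 0, 0, 2 and 0, and without dot1 replicate 2 there were 0, 0, 1 and 0. Heat shock chaperones called numbered 2, 2 and 1 without those 3 arrays in the same order, and amino acid genes 1, 1 and 0. Median centring gave 11 called respiratory chain genes and 5 ribosome biogenesis genes, and quantile normalization gave 12 of the former. Genes whose 2 arrays lay apart from both wt arrays made up 42.6% of all genes, where chance gives 33.3%.

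In swi4 the largest falls included SBF targets. TOS6, which encodes a cell wall protein and was not on the SBF list, was 25.2-fold lower (−4.65 ± 0.09, adjusted p = 3.82e-06). The SBF targets SVS1, a cell wall gene, and CSI2 were 7.24-fold (−2.86 ± 0.14) and 5.73-fold lower (−2.52 ± 0.13). YHP1, a homeobox repressor gene, was 5.32-fold lower (−2.41 ± 0.20). The G1 cyclin genes PCL1 (−2.06 ± 0.17), CLN1 (−1.42 ± 0.17) and CLN2 also fell. So did YOX1 (−1.71 ± 0.15), the second homeobox repressor gene, and PHO89, a phosphate transporter gene (4.80-fold lower, −2.26 ± 0.12). HSP26 rose 14-fold (3.81 ± 0.20), NCA3 4.35-fold (2.12 ± 0.16), the transaldolase gene NQM1 4.14-fold (2.05 ± 0.22) and the aldehyde dehydrogenase gene ALD3 4.03-fold (2.01 ± 0.22). In all, 281 genes rose and 382 fell, 74 and 62 of them by at least 2-fold. After median centring 426 rose and 299 fell, and after quantile normalization 456 and 361, so rises were then the more frequent.

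Of 20 SBF targets 9 fell in swi4 and 0 rose (12 fell adjusted over the list alone), and all 20 had negative changes, with a median of −0.49. For the SBF targets camera gave adjusted p = 1.49e-07, and adjusted p = 0.599 with an estimated correlation. Of 21 targets of the related factor MBF, 3 rose and 3 fell (4 and 3 adjusted over the list alone), among them the ribonucleotide reductase gene RNR1 (−1.26 ± 0.19). The MBF list did not pass (camera adjusted p = 0.625). Of 9 histone genes 5 fell (8 adjusted over the list alone), including HHT1 (−0.82 ± 0.10), HTB2 (−0.72 ± 0.10) and HTA1 (−0.54 ± 0.09). For the histone genes camera gave adjusted p = 1.36e-04, and adjusted p = 0.599 with an estimated correlation. In the CLB2 cluster of mitotic genes 5 of 13 fell (8 adjusted over the list alone), among them CDC5 (−1.48 ± 0.20), CLB1 (−1.40 ± 0.16) and CLB2 (−1.20 ± 0.23). For the CLB2 cluster camera gave adjusted p = 2.53e-04, and adjusted p = 0.766 with an estimated correlation. Of the 7 SBF and MBF subunit genes only SWI4 itself was called (1 adjusted over the list alone). Stress genes rose in swi4, 10 of 22 (12 adjusted over the list alone), among them ALD3, the catalase gene CTT1 (1.08 ± 0.15) and HSP12 (1.48 ± 0.38). For the stress list camera gave adjusted p = 9.57e-09, and adjusted p = 0.599 with an estimated correlation. Of 21 chaperone genes 6 rose, of 21 sulfur genes 11 and of 34 amino acid genes 9 (9, 14, and 12 up and 1 down adjusted over the list alone). Camera gave these lists adjusted p = 2.00e-07, 2.01e-08 and 4.26e-06, each with adjusted p = 0.481 with an estimated correlation. All 33 respiratory chain genes had positive changes (median 0.32), and 5 rose (17 adjusted over the list alone). For the respiratory chain camera gave adjusted p = 1.20e-11, and adjusted p = 0.481 with an estimated correlation. All 50 ribosome biogenesis genes had negative changes (median −0.62), and 4 fell (0 adjusted over the list alone and 25 at an unadjusted p under 0.05). For this list of 50 camera gave adjusted p = 3.27e-06, and adjusted p = 0.766 with an estimated correlation. Pheromone response genes fell, 3 of 14 (7 adjusted over the list alone), with KAR4 at −0.67 ± 0.13 and FIG1 at −0.54 ± 0.11. For the pheromone response list camera gave adjusted p = 0.0118, and adjusted p = 0.766 with an estimated correlation.

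The swi4 count of 663 became 1435 without wt replicate 1, 258 without wt replicate 2, 37 without swi4 replicate 1 and 54 without swi4 replicate 2. Without swi4 replicate 1 and without swi4 replicate 2, in turn, the called genes were 4 and 4 SBF targets, 0 and 0 histone genes and 0 and 1 CLB2 cluster genes. In the same order there were 2 and 2 stress genes, 2 and 3 chaperone genes, 2 and 2 sulfur genes, 2 and 2 amino acid genes, 0 and 0 respiratory chain genes, 0 and 0 ribosome biogenesis genes and 0 and 0 pheromone response genes. Without wt replicate 2 the called histone, CLB2 cluster and stress genes numbered 3, 2 and 5. The pheromone response, respiratory chain and ribosome biogenesis genes then numbered 1, 3 and 0. Without wt replicate 1 there were 28 ribosome biogenesis genes, 9 CLB2 cluster genes, 8 histone genes and 8 respiratory chain genes, and the pheromone response list no longer passed camera (adjusted p = 0.112). Scaling moved the respiratory chain genes to 11 after centring and 12 after quantile normalization, and the CLB2 cluster to 8 after centring. Of 97 calls of named genes, 22 were made whichever of the 4 arrays was left out, among them TOS6, SVS1, CSI2, YHP1, YOX1, PCL1, NRM1, PHO89, NCA3, HSP26 and SSA4. Genes with both arrays apart from both wt arrays made up 59.6%, against 33.3% by chance.

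In ard1 WSC4, which encodes a cell wall stress sensor, was 5.34-fold lower (−2.42 ± 0.11, adjusted p = 5.03e-04), FCY22, a purine and cytosine permease gene, 3.71-fold lower (−1.89 ± 0.16) and MIT1, a regulator of filamentous growth, 3.33-fold lower (−1.73 ± 0.12). HSP26 rose 10.4-fold (3.38 ± 0.20), OPT2 6.42-fold (2.68 ± 0.18) and ATG41 5.79-fold (2.53 ± 0.19). Other rises were those of FMP23 at 5.01-fold (2.33 ± 0.15), HPF1, a cell wall glycoprotein gene, at 4.04-fold (2.02 ± 0.10) and ARG1, an arginine synthesis gene, at 3.88-fold (1.96 ± 0.14). In all, 341 genes rose and 665 fell, 71 and 103 of them by at least 2-fold. Median centring gave 511 up and 508 down and quantile normalization 555 and 562.

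Of 5 alpha-specific genes 4 fell in ard1 (4 adjusted over the list alone): the a-factor receptor gene STE3 (−1.15 ± 0.10), the agglutinin gene SAG1 (−0.70 ± 0.12), and the pheromone genes MF(ALPHA)1 (−0.55 ± 0.09) and MF(ALPHA)2 (−0.43 ± 0.09), while AFB1 gave −0.18 ± 0.08. For the alpha-specific list camera gave adjusted p = 0.00205, and adjusted p = 0.481 with an estimated correlation. Of 14 pheromone response genes 8 fell (11 adjusted over the list alone), among them the cell fusion gene FUS1 (−1.54 ± 0.31), SST2, a brake on pheromone signalling (−1.42 ± 0.18), FIG1 (−1.36 ± 0.11) and AGA1 (−1.24 ± 0.19). For this pheromone response list camera gave adjusted p = 1.83e-05, and adjusted p = 0.482 with an estimated correlation. Of 11 haploid-specific genes 4 fell (4 adjusted over the list alone), FAR1, AXL1 (−0.63 ± 0.14), STE4 (−0.62 ± 0.14) and FUS3 (−0.57 ± 0.10), without passing camera (adjusted p = 0.0995). In the CLB2 cluster 8 of 13 fell (9 adjusted over the list alone), CLB2 by 1.09 ± 0.23 and SWI5 by 1.05 ± 0.19. For this cluster camera gave adjusted p = 0.00203, and adjusted p = 0.766 with an estimated correlation. Iron regulon genes rose, 10 of 23, and 2 fell (11 and 3 adjusted over the list alone), led by TIS11 (1.78 ± 0.19), an mRNA decay factor gene of iron starvation, and the siderophore uptake genes FIT2 (1.49 ± 0.11) and ARN1 (1.38 ± 0.11). For the iron regulon camera gave adjusted p = 2.70e-05, and adjusted p = 0.481 with an estimated correlation. Of 34 amino acid genes 16 rose and 1 fell, of 21 sulfur genes 12 rose and 1 fell and of 21 chaperone genes 9 rose (18 and 1, 13 and 1, and 10 adjusted over the list alone). Camera gave these 3 lists adjusted p = 8.47e-11, 1.04e-06 and 2.77e-07, each with adjusted p = 0.481 with an estimated correlation. Respiratory chain genes fell in ard1, 10 of 33 (13 down and 1 up adjusted over the list alone), with QCR10 at −0.97 ± 0.15, SDH1 at −0.86 ± 0.15 and CYT1 at −0.82 ± 0.12. For these respiratory genes camera gave adjusted p = 7.16e-04, and adjusted p = 0.766 with an estimated correlation. Stress genes were split, 3 up and 3 down of 22 (3 and 3 adjusted over the list alone; camera adjusted p = 0.575), with a median of −0.22, a mean of 0.02 and a downward camera direction. The trehalose synthesis genes TSL1 (−0.99) and TPS2 (−0.70) were among the falls.

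The ard1 count of 1006 was 985 without wt replicate 1, 954 without wt replicate 2, 285 without ard1 replicate 1 and 205 without ard1 replicate 2. Without ard1 replicate 1 and without ard1 replicate 2, in turn, the called falls were 1 and 1 alpha-specific genes, 6 and 2 pheromone response genes, 2 and 1 haploid-specific genes, 0 and 0 CLB2 cluster genes and 2 and 1 respiratory chain genes. The called rises were 6 and 6 iron genes, 10 and 9 amino acid genes, 3 and 5 sulfur genes and 4 and 4 chaperone genes. Without wt replicate 2 there were 4 CLB2 cluster genes and without wt replicate 1 there were 6 chaperone genes. Of 112 calls of named genes, 39 were made whichever of the 4 arrays was left out, among them WSC4, FCY22, MIT1, HSP26, OPT2, ATG41, FMP23, HPF1, ARG1, STE3, SST2, FIG1, FAR1, FIT2, ARN1, TIS11 and SVS1. Genes with both arrays apart from both wt arrays made up 57.0%, against 33.3% by chance.

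**Figure D2:**
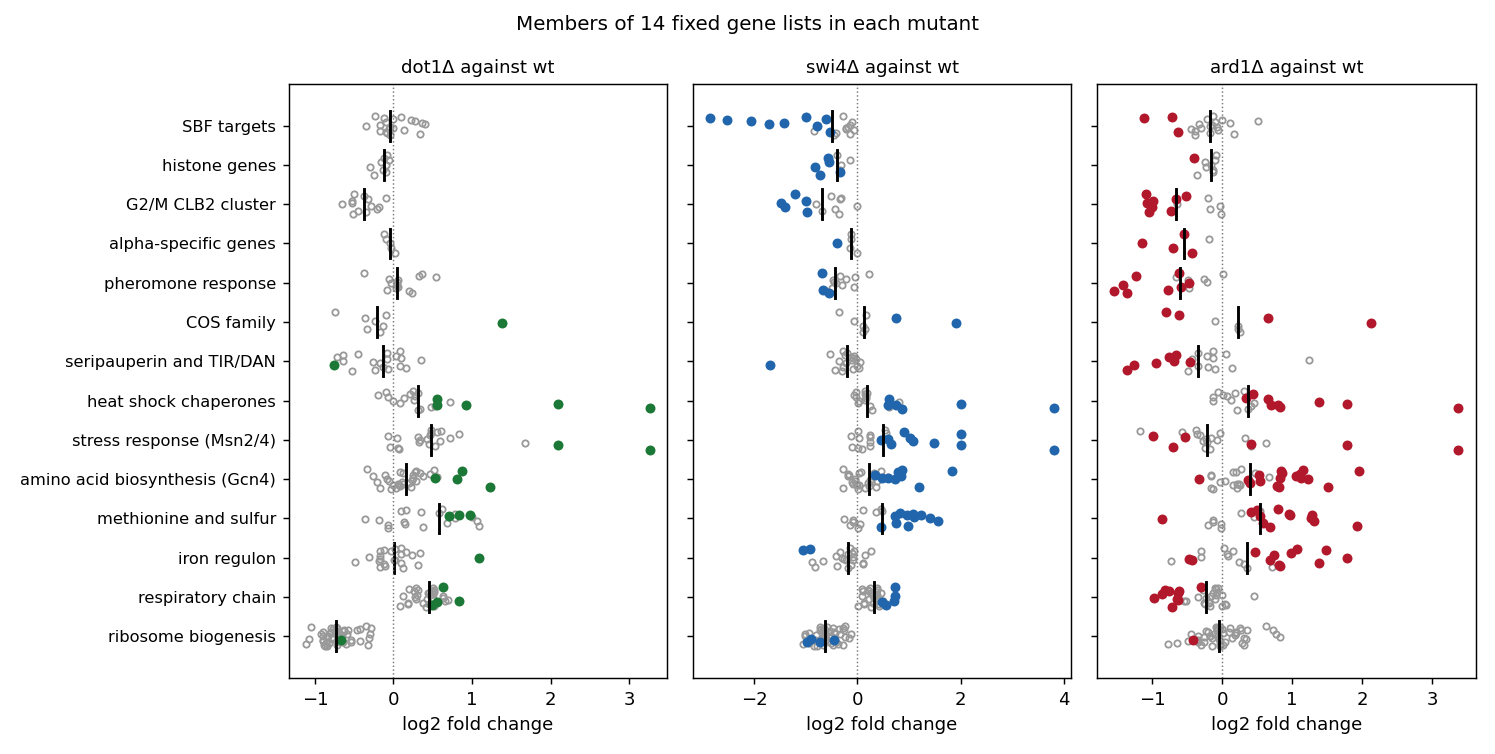
Change against wt (log2) of every measured member of 14 fixed gene lists in dot1, swi4 and ard1; each point is a gene, filled where called by limma, and the black bar is the list's median. The medians of the SBF targets and ribosome biogenesis genes in swi4 are −0.49 and −0.62, and that of the pheromone response genes in ard1 is −0.60.

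**Figure D3:**
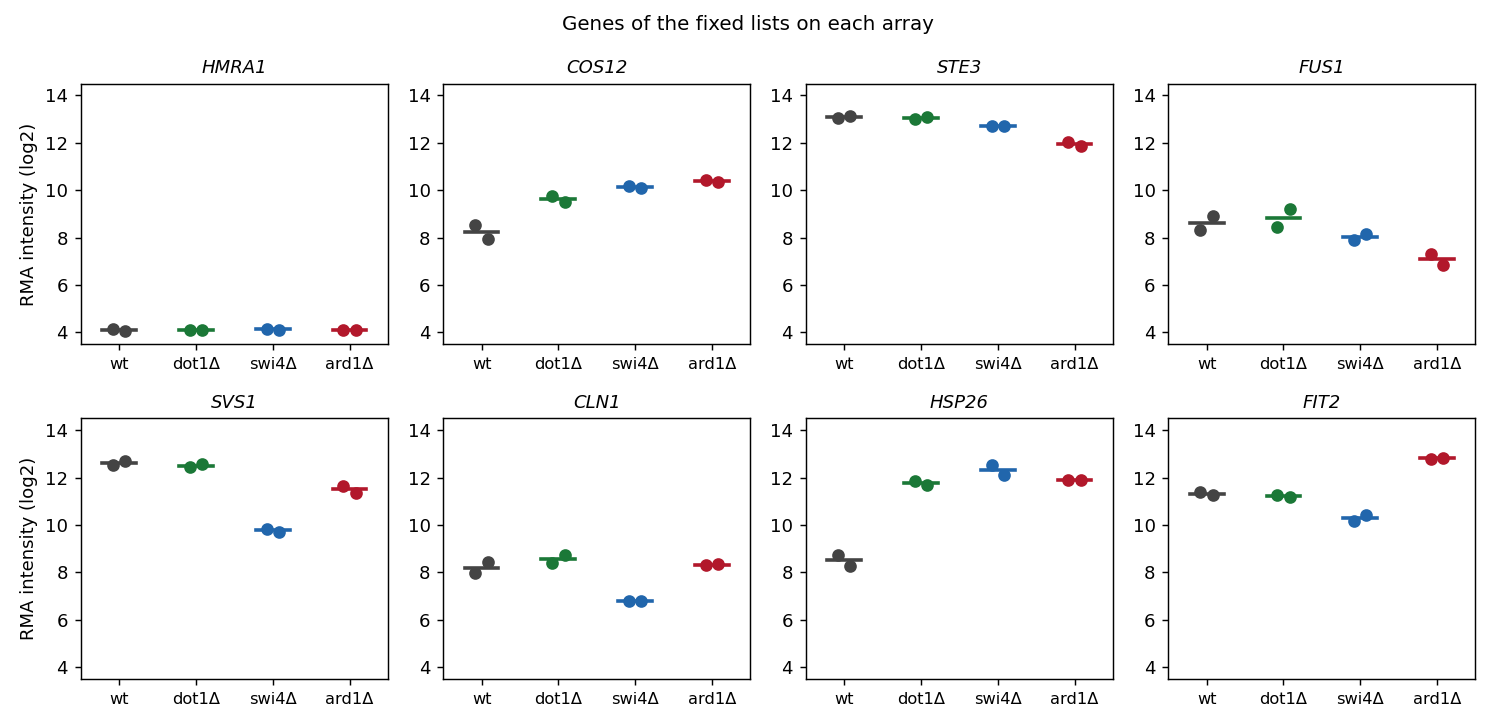
RMA intensity (log2) of 8 genes on each of the 8 arrays, by strain; points are arrays and bars are group means of 2 arrays. HMRA1 lies between 4.05 and 4.15 on every array, while HSP26 is higher in all 3 mutants, by 3.26, 3.81 and 3.38.

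Near the chromosome ends, genes moved both ways in every mutant. Of the 191 genes tested there, 78 had numbers 1 to 4 from the end of an arm and 113 had numbers 5 to 8. The 8 listed helicases of the Y' telomere elements were not among them, so the sequence nearest the ends is covered only in part. In dot1, 5 of 191 subtelomeric genes rose and 8 fell. SEO1, a permease gene (2.43 ± 0.31), COS12 (1.38 ± 0.19), MHT1 (1.27 ± 0.21), SRY1 (0.86) and REE1 (0.71) rose. YAR068W (−1.17), YAR066W (−0.98), the fluoride exporter genes FEX1 (−0.76) and FEX2 (−0.73), ARR2 (−0.73), YEL076C (−0.60), YBL113C (−0.56) and YFL067W (−0.49) fell. Of these, YAR066W, FEX1, YEL076C and YBL113C have shared probe sets. In swi4, 19 rose and 13 fell, with SEO1 (2.50 ± 0.31) and COS12 (1.91 ± 0.19) highest and PHO89 lowest (−2.26 ± 0.12). In ard1, 19 rose and 35 fell, led by COS12 (2.13 ± 0.19), the sulfate transporter gene SUL1 (1.93 ± 0.24) and SEO1 (1.90 ± 0.31), against YER187W (−1.50), ARR2 (−1.20) and BIO2 (−1.16). YFR057W, a gene beside a telomere that was chosen after its values were seen, was near the floor in wt (4.08) and changed by 0.10, −0.01 and 0.98 (SE 0.11) in dot1, swi4 and ard1. Its rise was called in ard1 alone (adjusted p = 0.00387), whichever of the 4 arrays was left out.

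Rises took in 2.62% of subtelomeric genes in dot1 against 1.07% of the 5258 other genes (Fisher's exact test, adjusted p = 0.0922), 9.95% against 4.98% in swi4 (adjusted p = 0.0196) and 9.95% against 6.12% in ard1 (adjusted p = 0.0915). Falls took in 4.19% against 1.24% in dot1 (adjusted p = 0.0225), 6.81% against 7.02% in swi4 (adjusted p = 1) and 18.3% against 12.0% in ard1 (adjusted p = 0.0383). The camera test of the set, unadjusted, gave p = 0.586, 0.0298 and 0.221, and p = 0.897, 0.612 and 0.772 with an estimated correlation. The median change of the subtelomeric genes was −0.09 in dot1, inside the range of −0.10 to −0.03 of matched random sets, 0.00 in swi4, above −0.14 to −0.04, and −0.16 in ard1, below −0.12 to −0.03. Adjusted over the list alone, 30, 41 and 57 were called. The excess of falls lost its unadjusted Fisher's exact p under 0.05 after median centring (p = 0.0623 in dot1 and 0.127 in ard1) and quantile normalization (p = 0.172 and 0.398), and the excess of rises in swi4 after quantile normalization (p = 0.111). By the same Fisher's exact test the falls in ard1 lost it too without the dimmest 25% of genes (p = 0.226), without repeated families (p = 0.0705), with 4 genes per arm (p = 0.222) and without wt replicate 1 (p = 0.665), ard1 replicate 1 (p = 0.112) or ard1 replicate 2 (p = 0.218). By Fisher's exact test the falls in dot1 lost it with 16 genes per arm (p = 0.0761), with trend and robust options (p = 0.169) and without wt replicate 1 (p = 0.204), and the rises in swi4 with 4 genes per arm (p = 0.122). With only 2 groups or without the other arrays of dot1 and wt the falls called in dot1 were 1 or fewer, and without either swi4 array the rises called in swi4 were 2 or fewer, too few to test. In swi4 falls were in excess by Fisher's exact test with only 2 groups (p = 0.00942) and without wt replicate 2 (p = 0.00470), swi4 replicate 1 (p = 0.00548) or swi4 replicate 2 (p = 0.00350). They were in deficit without wt replicate 1, 8.90% against 20.5% (Fisher's exact test, p = 2.95e-05). In dot1 rises had an unadjusted Fisher's exact p under 0.05 without the dimmest 25% of genes (p = 3.05e-04), with 16 genes per arm (p = 7.38e-04) and with trend and robust options (p = 0.0146). In ard1 the unadjusted Fisher's exact p of the rises, 0.0458 with all arrays, ranged over the settings from 6.57e-04 without wt replicate 1 to 0.808 after quantile normalization. It was above 0.05 also after median centring (0.311), without wt replicate 2 (0.792), ard1 replicate 1 (0.551) or ard1 replicate 2 (0.195), without the dimmest 25% of genes (0.0807) and with 4 genes per arm (0.152). The called numbers in dot1 were 26, 0, 1 and 0 without wt replicate 1, wt replicate 2, dot1 replicate 1 and dot1 replicate 2 (limma, with 54 and 51 genes at an unadjusted p under 0.05 where 0 were called). They were 42, 22, 4 and 7 in swi4 for the same order of arrays, and 43, 49, 15 and 12 in ard1.

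**Figure D4:**
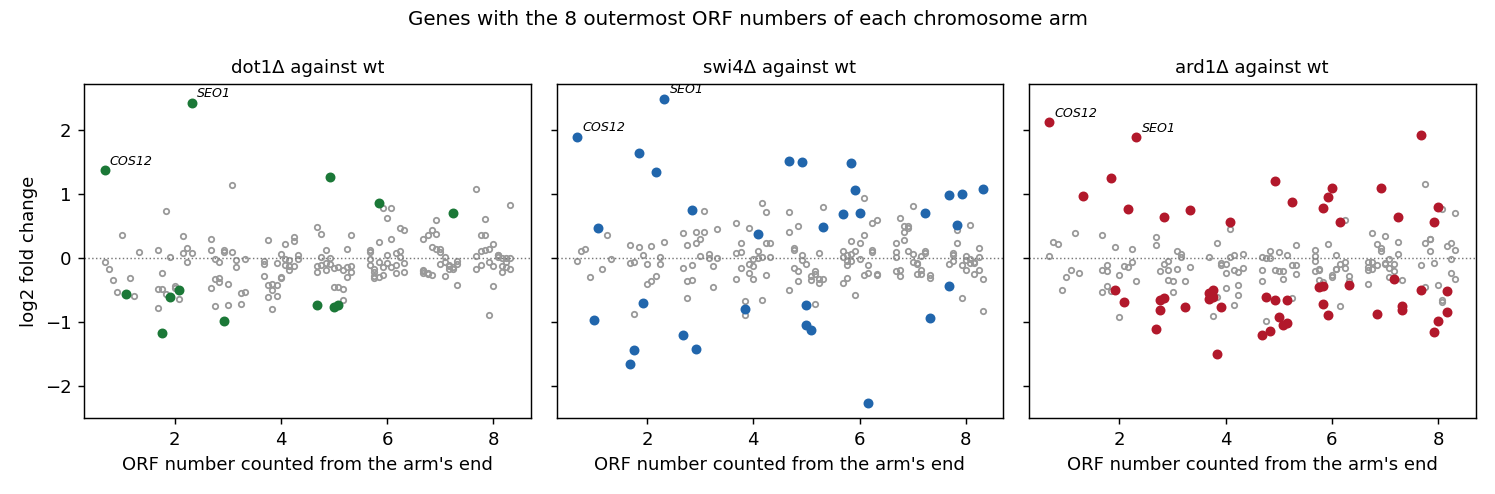
Change against wt (log2) of the 191 subtelomeric genes by their gene number counted from the end of the chromosome arm, in dot1, swi4 and ard1; each point is a gene, filled where called by limma. Called genes lie on both sides of 0 in each mutant, 5 up and 8 down in dot1, 19 and 13 in swi4, 19 and 35 in ard1, with SEO1 and COS12 marked.

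TOS6 was lower in swi4 than in dot1 or ard1, and WSC4 was lower in ard1 than in dot1, when the mutants were set directly against each other. Between swi4 and dot1, 20 genes were higher and 35 lower in swi4. The lowest were TOS6 (−4.68), SVS1 (−2.74), CSI2 (−2.74), YHP1 (−2.39) and PCL1 (−2.34), and DOT1 itself (3.12), NCA3 (3.11) and THI13 (1.73) were high. Between ard1 and dot1, 309 were higher and 460 lower in ard1 (496 and 473 after median centring). WSC4 (−2.32), AFR1 (−2.03), USV1 (−1.92), FUS1 (−1.74) and QCR10 (−1.60) were among the lowest and YOR338W (2.21), ATG41 (2.19) and PDH1 (1.82) among the highest. Between swi4 and ard1, 494 were higher and 338 lower in swi4. Here TOS6 (−4.60), PHO89 (−2.83), PCL1 (−2.58), FIT2 (−2.54) and HPF1 (−2.46) were low and YNL194C (2.45), ALD3 (2.38) and NQM1 (1.94) high. These genes were taken from the largest differences after the values were seen. Counts without single arrays were 292, 518, 84 and 102 for ard1 against dot1 (dot1 replicates 1 and 2, then ard1 replicates 1 and 2). They were 38, 14, 13 and 12 for swi4 against dot1 (dot1 replicates, then swi4 replicates), and 56, 193, 143 and 166 for swi4 against ard1 (swi4 replicates, then ard1 replicates). Genes with both arrays of 1 mutant apart from those of the other made up 61.4%, 44.4% and 74.1% in the same order, against 33.3% by chance.

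The lists differed between mutants as well, by camera adjusted over 99 tests. SBF targets were lower in swi4 than in dot1, 7 of 20 called (adjusted p = 2.25e-15; adjusted p = 0.428 with an estimated correlation), and lower than in ard1, 7 called (adjusted p = 6.60e-04; adjusted p = 0.717 with an estimated correlation). Pheromone response genes were lower in ard1 than in dot1, 9 of 14 called, as were respiratory chain genes, 26 of 33 called (adjusted p = 9.20e-08 and 3.47e-18; each with adjusted p = 0.428 with an estimated correlation). Ribosome biogenesis genes were higher in ard1 than in dot1, with a median difference of 0.69 and 13 of 50 called (adjusted p = 9.14e-10; adjusted p = 0.731 with an estimated correlation). Iron genes were lower in swi4 than in ard1, 12 of 23 called (adjusted p = 3.11e-06; adjusted p = 0.428 with an estimated correlation). Near chromosome ends, 6 of 191 genes, COS8, YBL113C, YFL068W, YFL067W, YPL278C and THI13, were higher in swi4 than in dot1. They made up 3.14% against 0.266% of other genes (Fisher's exact test, adjusted p = 2.65e-04). The probe sets of YBL113C, YPL278C and THI13 are shared between transcripts, so the genes counted may not be independent. No alternative setting was run for this test. The camera p for the 191 genes was 0.00162 and p = 0.470 with an estimated correlation. Changes that were called against wt and also differed from both other mutants were counted. They numbered 0 up and 4 down in dot1, 12 and 21 in swi4, and 100 and 222 in ard1. With the replicate number as a block, dot1 had 7 up and 9 down. The 4 in dot1 without the block were DOT1, NCA3 (−0.98 ± 0.16), YBL113C (−0.56 ± 0.09, a shared probe set) and YFL067W (−0.49). The last 3 were chosen after their values were seen. At an unadjusted p under 0.05 in each of the 3 limma comparisons, 21 genes were higher and 40 lower in dot1 than in all other strains. Without wt replicate 1 the dot1 numbers were 4 up and 4 down, and leaving out any 1 of the other 7 arrays, 0 up and 1 down.

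A set of genes moved the same way in all 3 mutants: 38 rose and 47 fell in each. HSP26, SEO1, OPT2, SSA4, COS12, HIS4, ARG1, MET14 and MET1 were among the rises. YMR230W-A, YDR042C, ATF2, ZPS1, DBP2 and TIR1, a cell wall mannoprotein gene, were among the falls. Independent lists of these sizes would share 0.197 rises and 0.625 falls, numbers that leave out what the shared wt arrays add. For 23 of the rises and 40 of the falls no difference between mutants was called. The shared numbers were 85 up and 204 down without wt replicate 1, and 7 and 2 without wt replicate 2. They were 6 and 3 without dot1 replicate 1, 2 and 1 without dot1 replicate 2, 4 and 1 without either swi4 array, and 6 and 3 without either ard1 array.

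Across genes, which are not independent replicates, the changes of dot1 and swi4 correlated at r = 0.741, those of dot1 and ard1 at 0.355 and those of swi4 and ard1 at 0.410. In 100 simulations of unchanged groups set against shared, simulated wt arrays, r was 0.496. The covariances were 0.0962, 0.0477 and 0.0684 against 0.0130 simulated, differences of 0.0832, 0.0347 and 0.0554. The simulations gave all groups the same spread for a gene. The real wt replicates differed most, with an SD of 0.32 against 0.30, 0.14 and 0.17 in dot1, swi4 and ard1. The simulated covariance may thus be too low, and the differences from it too large. The sign was the same for 79.9%, 65.0% and 66.6% of genes against 66.6% simulated. Genes up in both of a pair numbered 55, 41 and 113 (3.15, 3.82 and 17.6 for independent lists), genes down in both 62, 49 and 186 (5.12, 8.91 and 46.6), and genes called in opposite directions 3, 6 and 16. Part of the excess may come from the shared controls, which are too few to be split.

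Of 14 silencing factor genes 0 were called in dot1 (3 down adjusted over the list alone). In swi4 3 fell, RAP1 (−0.92 ± 0.11), SIR2 (−0.76 ± 0.12) and SAS5 (−0.58 ± 0.09) (3 adjusted over the list alone). In ard1 2 fell, RIF2 (−0.69 ± 0.17) and YKU70 (−0.48 ± 0.13) (0 adjusted over the list alone), and camera did not pass (for swi4, adjusted p = 0.185). Of 19 genes of histone methylation and H2B ubiquitination, 0, 3 and 1 fell (0, 3 and 1 adjusted over the list alone), including SWD2 in swi4 (−0.47 ± 0.10), where median centring left 0 called. Among 8 N-terminal acetyltransferase genes NAT3 rose in swi4 (0.58 ± 0.11) and ard1 (0.45 ± 0.11), and MAK3 fell in swi4 (−0.66 ± 0.14). NAT1, the partner of Ard1 in NatA, fell in ard1 (−0.56 ± 0.12), and the numbers adjusted over the list alone were the same. In the COS family of 8, COS12 rose in each mutant, COS8 rose in swi4 (0.75 ± 0.16) and ard1 (0.65 ± 0.16), and COS10 (−0.81 ± 0.16) and COS9 (−0.61 ± 0.14) fell in ard1 (1 up and 2 down, 2 and 0, and 2 and 2 adjusted over the list alone). The COS list passed camera in swi4 (adjusted p = 0.0341; adjusted p = 0.766 with an estimated correlation). Of 19 seripauperin and TIR/DAN genes 1, 1 and 7 fell (4 down, 1 down, and 7 down and 1 up adjusted over the list alone), among them TIR1 (−0.76, −1.70 and −1.26). After median centring or quantile normalization 4 fell in ard1 (for ard1, camera adjusted p = 0.0181; adjusted p = 0.766 with an estimated correlation). Of 4 flocculin genes FLO10 (−1.01 ± 0.20) and FLO11 (−0.66 ± 0.15) fell in ard1 (4 adjusted over the list alone), 1 of them after median centring. For the flocculins camera gave adjusted p = 0.0341, and adjusted p = 0.766 with an estimated correlation. Without wt replicate 1, 4 silencing factor genes were called lower in dot1, the 2 flocculin calls in ard1 were lost, and camera no longer passed in ard1 for the flocculins (adjusted p = 0.232) or the seripauperin and TIR/DAN genes (adjusted p = 0.464). Nor did it pass for these 2 lists without ard1 replicate 2 (adjusted p = 0.0775 and 0.184), or for the COS family in swi4 without wt replicate 2 (adjusted p = 0.259) or swi4 replicate 1 (adjusted p = 0.102). The silencing factor calls in swi4 and ard1 were lost when either array of the mutant was left out, and either scaling left 1 of the 2 falls in ard1 of the silencing factors and of the COS family.

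Of 16 sporulation genes HOP1 (0.90 ± 0.18) and DIT1 (0.78) rose and SPS1 (−1.34 ± 0.30) fell in swi4 (3 and 2 adjusted over the list alone). SPO11 (−0.78 ± 0.14) and IME1 (−0.56 ± 0.10) fell in ard1 (2 adjusted over the list alone). For the sporulation list in ard1 camera gave adjusted p = 0.0181, and adjusted p = 0.599 with an estimated correlation. Among 16 phosphate genes PHO89, PHO5 (−1.47 ± 0.13) and PHO11 (−0.96 ± 0.22, a shared probe set) fell in swi4 (5 adjusted over the list alone). In ard1 PHO89 rose (0.57 ± 0.12) and 2 fell (1 and 2 adjusted over the list alone). In dot1 0 were called (1 up adjusted over the list alone), with camera adjusted p = 0.00338 upward and adjusted p = 0.766 with an estimated correlation. Iron genes outside ard1 gave TIS11 up in dot1 (1.08 ± 0.19) and FIT2 (−1.05 ± 0.11) and FIT3 (−0.93 ± 0.12) down in swi4 (1 and 5 adjusted over the list alone). Of 128 cytosolic ribosomal protein genes 0, 3 and 5 rose (0, 0 and 2 adjusted over the list alone), among them RPL22B in ard1 (1.30 ± 0.15), with medians of 0.05, 0.07 and 0.07. Camera gave them adjusted p = 7.19e-06, 9.09e-07 and 4.39e-06, each with adjusted p = 0.766 with an estimated correlation. After median centring 7 rose in swi4 and 10 in ard1. Ribosome biogenesis genes in ard1 had a median of −0.04, which turned to 0.04 after centring and 0.01 after quantile normalization, with 1 called (0 adjusted over the list alone; camera adjusted p = 0.521 upward). Of 32 proteasome genes 0, 2 and 1 fell (0, 2 and 0 adjusted over the list alone), with camera passing in dot1 (adjusted p = 0.00205) and swi4 (adjusted p = 0.00226), each with adjusted p = 0.789 with an estimated correlation. Without wt replicate 1 the proteasome falls called were 8, 19 and 5, and ard1 then passed camera too (adjusted p = 9.46e-04), while without wt replicate 2 camera passed in none of the mutants (adjusted p = 0.178, 0.0532 and 0.852). Camera also failed for the sporulation list in ard1 without wt replicate 1 (adjusted p = 0.189) or ard1 replicate 2 (adjusted p = 0.108), and for the phosphate list in dot1 without dot1 replicate 2 (adjusted p = 0.113).

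In dot1 the MBF targets (0 of 21 called; 5 down at an unadjusted p under 0.05) and the CLB2 cluster (0 of 13; 5 down) had no called member and 0 adjusted over the list alone. Their medians were −0.26 and −0.37 and their camera adjusted p = 0.0455 and 0.0119 (adjusted p = 0.794 and 0.766 with an estimated correlation). Without wt replicate 1, 6 MBF targets and 6 CLB2 cluster genes were called lower in dot1, while camera passed for neither list without wt replicate 2 (adjusted p = 0.182 and 0.124) or dot1 replicate 1 (adjusted p = 0.371 and 0.284). SBF targets, SBF and MBF subunits, histone genes and the pheromone, alpha-specific, haploid-specific and sporulation lists had 0 called in dot1, also adjusted over the list alone, and did not pass camera. Without wt replicate 1, 1 SBF target, 1 histone gene and 1 pheromone response gene were called lower there, and without dot1 replicate 1 camera passed for the SBF targets (adjusted p = 0.0461) and pheromone response genes (adjusted p = 0.00476). Limma called 0 of 16 glycolysis genes in every mutant (0 adjusted over the list alone; 1, 0 and 1 at an unadjusted p under 0.05). Of 17 hexose transporter genes SNF3 (−0.48 ± 0.09) and HXT17 (−0.42 ± 0.12, a shared probe set) fell in ard1 (1 adjusted over the list alone, and 1 called after either scaling) and 0 were called elsewhere. Of 20 gluconeogenesis and glyoxylate genes 1 rose in dot1, 3 rose and 2 fell in swi4, and 2 rose and 5 fell in ard1 (the same numbers adjusted over the list alone). MDH2 was up in all 3 (1.15, 1.12 and 0.48) and PCK1 (−1.04 ± 0.19) and ADY2 (−1.02 ± 0.16) were down in ard1. After median centring or quantile normalization the 2 falls in swi4 were lost, and quantile normalization left 1 rise and 3 falls in ard1. Of 7 auxotrophic marker genes HIS3 rose in swi4 (0.86 ± 0.10) and ard1 (1.15 ± 0.10) and MET17 in ard1 (0.41 ± 0.10), with 2 up and 1 down, 2 up, and 2 up adjusted over the list alone. Of 15 cell wall integrity genes 0 were called in dot1, 1 rose and 2 fell in swi4, and 2 rose and 2 fell in ard1 (1 and 1, 3 and 2, and 2 and 4 adjusted over the list alone). CWP1 (−0.51 and −1.04) and CHS3 (−0.49 and −0.65) were down in both and PIR3 was up in swi4 (1.42 ± 0.17). Of SBF targets 3 fell in ard1, of MBF targets 3, of histone genes 1, and of the SBF and MBF subunits STB1 (−0.41 ± 0.10) and WHI5 (−0.38 ± 0.10) (3, 2, 1 and 2 adjusted over the list alone), without passing camera. Both subunit calls were lost after median centring and after quantile normalization, and the histone call after median centring. In swi4, 1 alpha-specific gene, STE3 (−0.40 ± 0.10), fell and 1 haploid-specific gene rose (the same numbers adjusted over the list alone), without passing camera, and the call of STE3 was lost after median centring.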

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

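The tests on the reporter probe sets and on the genes shared by the 3 mutants were chosen only after the results were seen. The arrays carry 47 reporter probe sets, which the comparisons of genes left out and whose sequences are not named in the tables used here. A signal above the wt arrays appeared in some of them, by at least 2-fold with an adjusted p under 0.05 from limma. A probe set for 1 reporter sequence was higher by 9.98 in dot1, 9.97 in swi4 and 10.03 in ard1 on the log2 scale. Its wt arrays were at 4.60 and 4.26 and the 6 mutant arrays between 14.38 and 14.47, while another probe set of the same sequence stayed between 4.76 and 4.92 on all 8 arrays. The wt arrays lay near the floor, so these differences are lower bounds. Probe sets for a second sequence were higher by 1.26 in dot1, by 1.14 and 1.34 in swi4, and by 1.11, 1.68, 1.46 and 1.90 in ard1. A probe set for a further sequence was higher by 1.24 in swi4 and 1.48 in ard1. In 2 of the 47 reporter probe sets, every mutant array lay at least 1 above both wt arrays. Of the 98 control and reporter probe sets, 1 fell by at least 2-fold in ard1 and 0 did in dot1 and swi4. Among the 218 unnamed probe sets, 2 rose and 0 fell in dot1, 6 and 2 in swi4, and 6 and 6 in ard1 by at least 2-fold.

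The 38 genes that rose and the 47 that fell in all 3 mutants were weighed against a deviant wt array and a difference between strains. The rises were not confined to the comparison with wt replicate 2. The 85 rises called without wt replicate 1 still lay a median of 0.663 above that array, which had no part in choosing them (quartiles 0.405 to 0.957), against 0.928 above replicate 2, and 83 of 85 kept their direction. The 204 falls chosen in the same way lay a median of 0.318 below replicate 1 (195 of 204 in the same direction) against 0.707 below replicate 2, so wt replicate 2 may account for part of the falls. The mutant arrays served both to choose these genes and to measure them, which favours the called direction. Their mean pools both replicate numbers, and deviations of same-numbered arrays correlated between groups (r of 0.351 to 0.754). These values thus cannot part a deviant wt array from a shift common to arrays of number 2. A difference between the wt strain and a parent or marker common to the mutants cannot be told apart from the deletions. The reporter's gap of at least 9.79 between the lowest mutant and the highest wt array separates the strains exactly as the deletions do. A selection marker is a candidate source of that signal. A response common to the 3 deletions stays open and was not tested.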

How the results depend on the processing

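Leaving out each array for the list counts and each mutant array for the overlap was chosen after seeing the data, and the other alternatives were planned. Of the 253 calls of named genes, 0 were reversed under any setting, but most settings could not reverse a call. Every called gene had its groups fully apart, so leaving out 1 array could not turn its sign. The block, the fit of 2 groups and the trend and robust options leave the change itself as it was. Only scaling or the mean of probe sets could turn a sign. The more frequent direction of change was not stable. Rises outnumbered falls in dot1 after median centring (119 against 114), quantile normalization (113 against 102) and without wt replicate 2 (7 against 4), and at an adjusted p under 0.01 (6 against 3). They did so in swi4 after median centring (426 against 299), quantile normalization (456 against 361), with only 2 groups (91 against 85), without wt replicate 2 (131 against 127), at 2-fold (74 against 62) and at an adjusted p under 0.01 (73 against 64), and in ard1 after median centring (511 against 508). For swi4 against dot1 the split became 21 up and 17 down without dot1 replicate 1, and for swi4 against ard1 1017 and 1210 with only 2 groups. Subtelomeric splits became 9 up and 7 down in dot1 without the dimmest 25% of genes and 13 and 10 with 16 genes per arm, and in swi4 0 and 4 without swi4 replicate 1 and 2 and 5 without replicate 2. With only the 2 groups compared, the counts called were 0 in dot1 (618 at an unadjusted p under 0.05 in limma), 176 in swi4 and 405 in ard1, 16 for swi4 against dot1 and 2227 for swi4 against ard1. Subtelomeric genes called in limma were then 0 (39 at an unadjusted p under 0.05), 17 and 29 in dot1, swi4 and ard1. DOT1 kept its fall of −3.31 without passing the threshold. In dot1 the count was 233 after median centring, 215 after quantile normalization, 216 without the dimmest 25% of genes and 333 with eBayes trend and robust options (21 subtelomeric). Without the dimmest genes 29 subtelomeric genes were called in ard1. At least 2-fold changes numbered 28, 136 and 174 in dot1, swi4 and ard1, and changes at an adjusted p under 0.01 numbered 9, 137 and 302. A subtelomere of 4 genes per arm held 7, 14 and 21 called genes and that of 16 genes held 23, 70 and 111. Of the 37 list tests that passed camera, 0 passed with an estimated correlation (8 of 99 had an unadjusted p under 0.05) and 24 passed fry, 22 of them among the 37. With only 2 groups the fit holds fewer samples and takes the spread from those groups alone. Calls fell from 134 to 0 in dot1 against wt but rose from 832 to 2227 for swi4 against ard1. Sample number alone therefore does not explain them. The fit over 4 groups lends dot1 and wt the smaller replicate spread of swi4 and ard1. Stricter limits and other widths change counts by construction. For the other settings the cause was not tested.

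The replicate numbers were not taken to pair the samples, since the labels do not say that a number marks a shared day or batch and there are only 2 numbers. With the number as a block, 793 (267 up and 526 down), 1397 and 1517 genes were called in dot1, swi4 and ard1. Among these were 46 and 67 subtelomeric genes in dot1 and swi4. The unadjusted Fisher's exact p for the subtelomeric rises was then 0.0377 in dot1 and 0.103 in ard1. Between mutants, 1582, 153 and 1547 genes were called for ard1 against dot1, swi4 against dot1 and swi4 against ard1. Shared genes were 110 up and 188 down under the block, and 36 of its 38 passing lists were among the 37. Deviations of same-numbered arrays correlated between 0.351 and 0.754 over the 6 pairs of groups, a hint from the data, not the design.

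Without 1 array at a time, a lone array left in a group is assumed to vary like the other groups. Counts ranged from 4 to 807 in dot1, 37 to 1435 in swi4 and 205 to 985 in ard1, from 84 to 518 for ard1 against dot1, 12 to 38 for swi4 against dot1 and 56 to 193 for swi4 against ard1. Subtelomeric counts ranged from 0 to 26, 4 to 42 and 12 to 49, and passing lists from 33 to 42. The change of DOT1 ranged from −3.53 to −3.10, that of SWI4 from −0.93 to −0.89 and that of ARD1 from −5.43 to −5.02. The correlation of changes ranged from 0.607 to 0.832 for dot1 and swi4, 0.258 to 0.503 for dot1 and ard1 and 0.362 to 0.543 for swi4 and ard1. The share of rises among calls moved from 42.4% to 58.8% in swi4 and from 33.9% to 50.1% in ard1 after median centring, and from 40.2% to 51.2% for ard1 against dot1. For subtelomeric genes it moved from 35.2% to 47.8% in ard1 and from 38.5% to 50% in dot1 after quantile normalization. Of 253 calls of named genes, 127 were lost with only 2 groups, 96 without wt replicate 2, 21 after median centring, 19 after quantile normalization, 16 without wt replicate 1 and 8 with trend and robust options. Leaving out swi4 replicate 1 lost 74 of 97 such calls in swi4 and dot1 replicate 2 lost 41 of 44 in dot1, while leaving out the dimmest 25% of genes lost 0 of 205.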

Other observations

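The tests of the ribosome biogenesis and mating genes were chosen only after the results were seen. Ribosome biogenesis genes had a median change of −0.73 in dot1 and −0.62 in swi4, with 1 and 4 of 50 called by limma (27 and 0 adjusted over the list alone). For this list camera gave adjusted p = 4.19e-11 and 3.27e-06, each with adjusted p = 0.766 with an estimated correlation. Scaling of the arrays as the cause is argued against, since the median in dot1 was −0.66 after median centring. A growth state that differs from culture to culture cannot be told apart from the deletions. The mean of the list differed by 0.611 between the 2 wt arrays and by 0.583 between the 2 dot1 arrays, against −0.709 for dot1 minus wt and −0.601 for swi4 minus wt. Between arrays of the same number, however, dot1 minus wt was −0.695 and −0.723, and swi4 minus wt was −0.391 and −0.810, and the labels do not say whether a number marks a shared culture day. An effect of the deletions on growth stays open and was not tested.

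Alpha-specific and pheromone response genes had medians of −0.55 and −0.60 in ard1, with 4 of 5 and 8 of 14 called lower by limma (4 and 11 adjusted over the list alone). Camera gave adjusted p = 0.00205 and 1.83e-05, with adjusted p = 0.481 and adjusted p = 0.482 with an estimated correlation. The labels used here do not give the mating type. If the cultures were alpha cells, cells of type a mixed into the ard1 cultures would raise a-specific genes, whose median in ard1 was −0.19, so this source is argued against. Transcription of the a1 gene at HMR might lower haploid-specific genes. No rise of HMRA1 was called in ard1, where its change was 0.00 on the log2 scale (0.00468). Its probe set lay near the floor on all arrays. A floor does not hide a large rise, but no array here shows that this probe set responds to the transcript. This explanation therefore cannot be told apart from others. A change of signalling in the ard1 strain itself stays open and was not tested.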
